A study of Mus musculus with 2 samples.

How the data were processed

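Total RNA of 2 mouse Th17 cultures, 1 from WT and 1 from Cd69-/- OT-II mice, was profiled on 2 Agilent 1-colour miRNA arrays. Per the labels' protocols, 100 ng of RNA per sample was dephosphorylated, ligated to a Cy3-labelled nucleotide and hybridised. Groups were taken from the cell type given in the labels, and both samples carry replicate number 1. The title of the WT sample also marks it as a re-analysis, with no word on what was repeated. The Cd69-/- title has no such mark, so any effect of it cannot be told apart from genotype. Per the file headers, both arrays were read with Agilent Feature Extraction 10.1.1.1, and the slide, scan and protocol entries are the same for both, so the groups did not differ in them.

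Per the file headers, each spot has a processed intensity on a linear scale, with background subtracted and spatial trends removed within the array and no scaling between arrays, and values can be negative. The deposited scanner output also gives the raw median intensity of each spot and its local background, and a total gene signal that Feature Extraction sums per miRNA. The deposited value table of the authors holds 89 miRNAs per sample; its values run from 0.05 to 11.7 and, set against the total gene signal, are on a log2 scale (Pearson r across miRNAs 0.998 in WT and 0.995 in Cd69-/-, with slopes of 1.07 and 0.88). Its direction is that of the sample columns. How the authors normalized and centred these log2 values before they were deposited is not given in the sources used here; both columns have a median of 6.28 and 69 values occur in both, as quantile normalization would leave them. The submitters' processing notes name limma, without a version or role.

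Of 12493 spots per array, 11340 belong to 1672 probes of 566 mouse miRNAs; control and viral spots were left out of the comparisons. Spots that Feature Extraction marked as outliers were left out (386 in WT, 425 in Cd69-/-) and 0 miRNA spots were saturated. A probe counted as detected when over 0.5 of its remaining spots were marked well above background, which 152 probes were in WT and 110 in Cd69-/-. The processed intensity was divided by the array's 75th percentile over the 109 probes detected on both arrays (370.5 in WT, 366.4 in Cd69-/-) and then put on a log2 scale. Spots were averaged per probe, and probes detected on both arrays were averaged per miRNA. Of 44 miRNAs with more than 1 such probe, let-7b alone had probes on both sides of 0, and the widest gap between probes of a miRNA was 0.58, for miR-690. For miR-714, miR-107 and miR-652 a further probe was detected on the WT array only and was not averaged in. The log2 values of the 61 miRNAs had a Pearson r of 0.897 between arrays, across miRNAs, which are not independent replicates.

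The number of arrays limits the precision. With 1 array per group no test was run and no p-value is given; a difference counted when it reached 2-fold. The spot SD of a difference combines the SDs between spots of a probe on the arrays (median 0.14, from 0.04 to 0.31 in log2) and says nothing of the spread between cultures. A miRNA detected on 1 array has a bound: its mean normalized log2 level on the brighter array against the higher of the lowest detected signal and its own signal on the dimmer array.

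The comparison, the 22 lists (17 of pathways, families or clusters and 5 of markers of other cells), the alternatives and the rule for named miRNAs were fixed before the data were examined. The rule named up to 12 miRNAs furthest up and 12 furthest down among those at least 2-fold different with all probes on the same side of 0, the 4 largest bounds of at least 2-fold in each direction, the 2 members of each list with the largest difference in size, and 13 miRNAs of Th17 or T cell interest whatever their value; it gave 38 names. For the 11 lists with at least 3 members measured on both arrays, the median difference was placed among 10000 random lists of the same size, matched on mean level. Names are those of the array's design and can be old: a name without arm was taken for the dominant arm. Of the 25 miRNAs lower by 2-fold or detected on the WT array only, 22 matched a gene symbol in a RefSeq table of the GRCm38.p6 assembly, as did 52 of the other 55. The 3 without a match were miR-714, miR-689 and miR-715 in the first set, and miR-685, miR-720 and miR-801_v10.1 in the second. No genome build is given in the files, so no coordinates are reported.

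The alternatives fixed at that stage were scaling to the median, quantile normalization, no scaling, a stricter and a looser filter on dim probes, Feature Extraction's flag and total per miRNA, the median over spots, the brightest probe, and the authors' table. The intended normexp background correction (offset 50) needed the mean spot intensity, a column not used here, and was run on the median spot intensity instead; this and scaling to the bright control probes were chosen after seeing the data. The computations were tested on simulated spots first. Of 56 simulated miRNAs 20 were changed, and all 20 were called at 2-fold in the right direction with 0 false calls, a largest error of 0.21 in log2 and bounds for 5 of 5 silenced miRNAs. A planted list of 6 came out at percentile 99.5. Every planted change of a miRNA was beyond 2-fold, with as many up as down, and the noise was that between spots. The run thus checks the computations and gives no error rate for the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.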

Results

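MicroRNAs were measured in Th17 cultures grown from naive CD4 T cells of OT-II mice, whose transgenic T cell receptor recognises ovalbumin. The cultures came from wild-type (WT) or Cd69-/- animals. CD69 is a membrane receptor that lymphocytes display soon after activation. The cells had been taken from spleen and mesenteric lymph nodes and cultured with ovalbumin, TGF-beta and IL-6, cytokines that drive Th17 differentiation. Each genotype was represented by 1 sample on 1 Agilent 1-colour mouse miRNA array. With 1 array per group there are no replicates and no test was possible, so differences are given by size, and the SDs given for a miRNA are spreads between its spots on an array. The arrays carry miRNA probes, so Cd69 messenger RNA was not measured and the genotypes are those of the labels.

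Each array held 11340 spots for 566 mouse miRNAs. In the WT culture 79 miRNAs were well above background, against 62 in the Cd69-/- culture. Of these, 61 were well above background on both arrays through the same probe, 18 on the WT array only and 1 on the Cd69-/- array only. The dimmest probe that counted as detected had a signal of 24.4 on the WT array and 26.2 on the Cd69-/- array. The negative control spots had a median signal of 2.57 (SD 3.76, 656 spots) and 3.98 (SD 3.89, 638 spots).

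The comparison of the genotypes asks which miRNAs differ in amount when Th17 cells develop without CD69. Among the 61 miRNAs measured on both arrays, 7 were at least 2-fold lower in the Cd69-/- culture, 0 were at least 2-fold higher and 54 differed by less than 2-fold. The lower ones were miR-714, miR-689, miR-188-5p, miR-574-5p, miR-706, miR-1224 and miR-30b. Another 6 miRNAs seen on the WT array only were lower by at least 2-fold as a bound, led by miR-721, a miRNA described in Th17 cells of mice with myocarditis. The best-known T cell miRNAs differed less: miR-155, which favours Th17 differentiation, was 1.56-fold lower, and miR-150, a miRNA of mature lymphocytes that acts on Myb, was 1.55-fold higher, a difference that came to 0.01 in log2 when scaled to bright control probes.

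The largest difference was that of miR-714, 5.93-fold lower in the Cd69-/- culture (log2 difference -2.57, spot SD 0.14), with mean signals of 426 in WT and 72.4 in Cd69-/-; the log2 difference was -1.69 after normexp and -1.30 with no filter on dim probes. A further miR-714 probe was well above background on the WT array only, at 27.8 against -8.45. miR-689 was 4.57-fold lower (log2 difference -2.19, spot SD 0.11), with 388 in WT and 83.8 in Cd69-/-, and stood at -1.40 after normexp. Neither miR-714 nor miR-689 matched a RefSeq gene symbol. For miR-188-5p the 4 probes gave log2 differences from -2.05 to -1.89 and a mean of -2.00 (spot SD 0.18), or 3.99-fold lower. miR-574-5p was 3.52-fold lower (log2 difference -1.82, spot SD 0.17), its signal being 241 in WT and 71.9 in Cd69-/-, and stood at -1.16 after quantile normalization and -1.07 after normexp. miR-706 was 3.27-fold lower (log2 difference -1.71, spot SD 0.18), which rested on 1 probe with 5 spots per array. Its other probes were detected on neither array. miR-1224, a miRNA spliced from a short intron, was 2.14-fold lower, from a signal of 2967 (SD 328) in WT to 1410 (SD 129) in Cd69-/-. Its log2 difference of -1.10 (spot SD 0.13) lay within 1 spot SD of the 2-fold line. miR-30b also rested on 1 probe, with another detected on neither array. Its 2.03-fold lower level (log2 difference -1.02, spot SD 0.26) also lay within 1 spot SD of the 2-fold line.

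**Figure D1:**
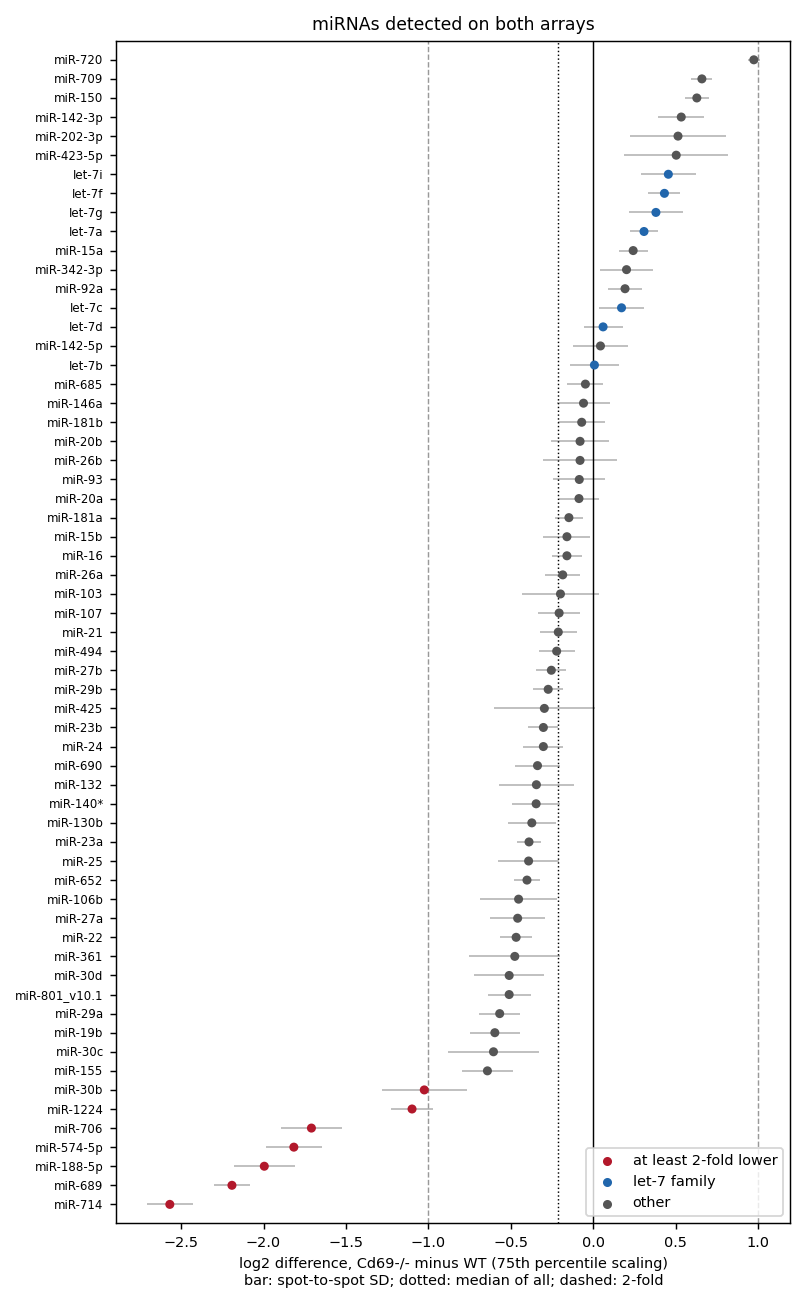
Log2 difference, Cd69-/- minus WT, of each of the 61 miRNAs well above background on both arrays; bars are the spot-to-spot SD, the dotted line is the median of all (-0.21) and dashed lines mark 2-fold. The 7 miRNAs in red lie at or below -1.02, from miR-714 at -2.57 to miR-30b, and the let-7 members in blue lie above 0, although their median is -0.31 when scaled to bright control probes. The lowest let-7 member, let-7b, lies at 0.0075 (spot SD 0.15).

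At the higher end stood miR-720, now regarded as a tRNA fragment, with a log2 difference of 0.97 (spot SD 0.04), and miR-709 with 0.66 (spot SD 0.06). Both were singled out after their values were seen. In the authors' deposited table they stood at 1.20 and 0.99. Scaling to bright control probes lowers both by the same amount in log2 as it lowers miR-150. miR-150 had a signal of 229 (SD 6.86) in WT and 344 (SD 14.1) in Cd69-/-, a log2 difference of 0.63 (spot SD 0.07) that was 0.44 after normexp and 0.01 when scaled to bright control probes. miR-142-3p, abundant in all blood cells, had 275 (SD 12.9) and 395 (SD 37.6), a log2 difference of 0.53 (spot SD 0.14) that was -0.09 when scaled to bright control probes. Of all 61 miRNAs, 9 lay above 0 and 26 below 0 by more than 2 spot SDs, which is larger than the error between spots and has no replicate check.

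The scaling between the arrays moved the whole set, so directions near 0 are relative. With scaling to the 75th percentile, 17 miRNAs were above 0 and 44 below, and the median of all was -0.21. The split was 35 above and 26 below when scaled to the median (median of all 0.09), 46 and 15 after quantile normalization (0.41), and 3 and 58 when scaled to bright control probes (-0.83). In the authors' deposited table it was 47 and 17 (0.33), with miR-801_v10.1 at 0, among the 65 miRNAs that Feature Extraction counted as detected on both arrays. Counts at 2-fold moved with it: 8 miRNAs were higher and 4 lower after quantile normalization, and 20 were lower when scaled to bright control probes. miR-714, miR-689 and miR-574-5p stayed at least 2-fold lower under each of the 12 alternatives tried, and miR-188-5p under 11 of them (-1.04 after quantile normalization), the exception being normexp with -0.86. Not all 12 could move these values: miR-689, miR-574-5p and miR-188-5p kept theirs exactly with no filter and with Feature Extraction's flag. The other 3 lost the call more often: miR-1224 kept it under 8 of 12 (-0.78 after quantile normalization, -0.80 when scaled to the median), miR-706 under 6 of the 9 that gave a value (-0.74 after quantile normalization, -0.43 with no filter on dim probes) and miR-30b under 6 of 11 (-0.13 after quantile normalization). With no filter, the probes of a miRNA detected on neither array enter its mean with a difference near 0 by construction.

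The 18 miRNAs seen on the WT array only included a group with clear WT signals and none in the Cd69-/- culture. miR-721 had a mean signal of 206 (SD 7.59, 20 spots of 4 probes) in WT and -8.46 (SD 3.25, 19 spots) in Cd69-/-, which puts it at least 7.76-fold lower there. miR-483, encoded within Igf2, read 129 in WT and -9.95 in Cd69-/-, at least 4.38-fold lower. miR-669c, from the large rodent cluster inside Sfmbt2, read 103 and 9.60, at least 3.87-fold lower. miR-468 read 63.3 and -1.58, at least 2.38-fold lower. miR-466c-5p and miR-669a, named after their values were seen, had bounds of at least 2.36-fold and at least 2.23-fold. For 9 of the 18 the mean Cd69-/- signal was below 0. The single miRNA seen on the Cd69-/- array only was miR-34a, a target of p53, with 36.5 against 21.1 in WT, at least 1.49-fold higher. Each bound sets the normalized level on the brighter array against the higher of the lowest detected signal and the probe's own signal on the dimmer array. The number of WT-only miRNAs bounded at 2-fold or more was 6 and came to 3 when scaled to the median, 2 after quantile normalization and 1 after normexp background correction, where miR-721 remained with a log2 bound of 1.43. The log2 bound of miR-483 was then 0.93, that of miR-669c 0.78 (0.87 after quantile normalization) and that of miR-468 0.42 (0.16 after quantile normalization), each under 2-fold.

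**Figure D2:**
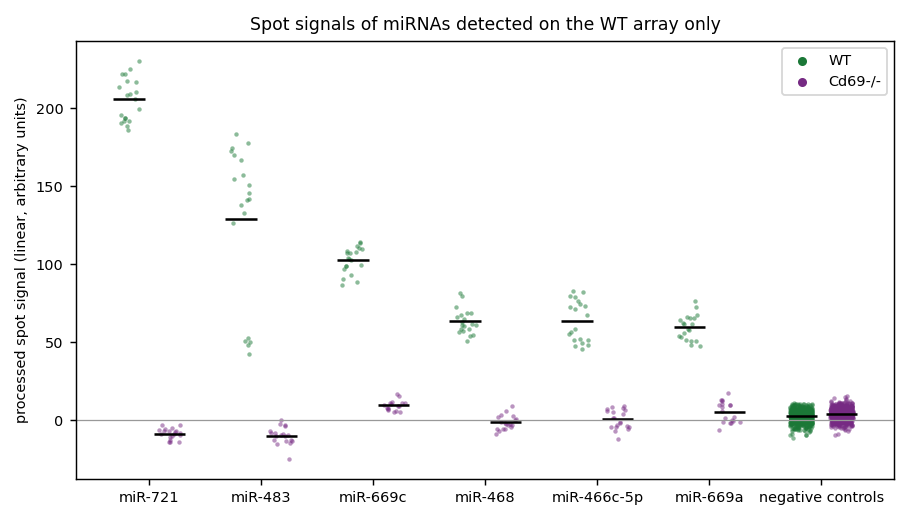
Processed spot signal (linear, arbitrary units) of the 6 miRNAs seen on the WT array only with a bound of at least 2-fold, beside the negative control spots; each point is a spot and the black line is the mean. The miR-721 spots average 206 in WT and -8.46 in Cd69-/-, and the negative controls have medians of 2.57 and 3.98.

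Of the 12 listed miRNAs described as promoting Th17 differentiation, 4 were measured on both arrays and 0 of them differed by 2-fold. All 4 lay below 0 with this scaling, and the list's median of -0.45, or -0.23 relative to all miRNAs, was below 0 under 11 of the 12 alternatives (-0.06 after quantile normalization) and 0.00 with no filter on dim probes. miR-155 had a signal of 405 (SD 21.5) in WT and 259 (SD 24.5) in Cd69-/-, a log2 difference of -0.64 (spot SD 0.15) that ranged from -1.26 to -0.34 over the alternatives. miR-19b, a member of the miR-17~92 cluster, differed by -0.60 (spot SD 0.15; -0.02 after quantile normalization and -0.13 in the authors' deposited table), and miR-21 by -0.21 (spot SD 0.11), the same as the median of all, or 0.09 when scaled to the median. miR-326 and miR-301a, both known to support Th17 cells, were not well above background on either array, although Feature Extraction's own flag per miRNA counted miR-301a as detected on both and the authors' deposited table put it higher in Cd69-/-, by 2.496 in log2. miR-183, miR-96 and miR-182, a cluster active in Th17 cells, were also not well above background on either array. The list's median stood at percentile 9.92 of 10000 random lists of like size and level, a description of these 2 samples.

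Of the 9 listed miRNAs described as restraining Th17 differentiation, 5 were measured on both arrays, with 0 differing by 2-fold. Their median was -0.08, or 0.13 relative to all miRNAs (percentile 76.7), and turned above 0 after quantile normalization (0.70), when scaled to the median (0.22) and in the authors' deposited table (0.60). let-7f differed by 0.43 (spot SD 0.10; -0.19 when scaled to bright control probes), miR-26a by -0.18 (spot SD 0.10; 0.47 after quantile normalization) and miR-146a, a brake on NF-kappaB signalling, by -0.06 (spot SD 0.16). For miR-146a the difference became 1.03 after quantile normalization and 1.04 in the authors' deposited table. miR-18a passed the detection rule on the WT array only, at 27.3 with 0.6 of its spots well above background against 25.4 with 0.5. Feature Extraction's flag counted it as detected on both, and the authors' deposited table put it higher in Cd69-/-, by 0.97 in log2. miR-10a was not well above background on either array.

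Both T cell activation lists lay near the middle of the random lists. Of the 16 listed as induced by T cell activation, 6 were measured on both arrays and 0 differed by 2-fold. Their median was -0.15, or 0.06 relative to all (percentile 54.9), and was 0.24 after quantile normalization, 0.15 when scaled to the median and 0.42 in the authors' deposited table. miR-132 differed by -0.34 (spot SD 0.23), or 0.61 after quantile normalization. Of the 19 listed as abundant in resting T cells and lower after activation, 12 were measured on both arrays, with miR-30b at least 2-fold lower and the other 11 under 2-fold. Their median was -0.17, or 0.04 relative to all (percentile 68.2), and was 0.42 after quantile normalization, 0.13 when scaled to the median and 0.22 in the authors' deposited table. miR-150 and miR-30b were the members furthest from 0, at 0.63 and -1.02.

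All 7 measured let-7 miRNAs, which hold back growth and T cell activation, lay above 0 with this scaling, while their median was -0.31 when scaled to bright control probes. Of these, let-7b (0.0075, spot SD 0.15), let-7d (0.06, spot SD 0.12) and let-7c (0.17, spot SD 0.14) lay within 2 spot SDs of 0. let-7a, let-7g, let-7f and let-7i lay beyond. The family median was 0.31, or 0.52 relative to all miRNAs, at percentile 96.4, and 0 members reached 2-fold. let-7i differed by 0.46 (spot SD 0.17) and let-7f by 0.43. Scaling by a single factor cannot move the family relative to all miRNAs. That value was 0.10 after quantile normalization, 0.17 with no filter on dim probes and 0.24 in the authors' deposited table. With no filter the median of all miRNAs is 0 by construction, so part of that change comes from the reference. Members of this family are nearly identical in sequence and can share hybridisation, so values of single members are uncertain. The same holds for pairs such as miR-29a and miR-29b, miR-23a and miR-23b, miR-27a and miR-27b, miR-181a and miR-181b, and miR-30b and miR-30c. Random lists were drawn without regard to such likeness. The percentile of a family, here and below, can thus look more extreme than that of as many unrelated miRNAs.

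The miR-30 family had 3 of 5 members measured and a median of -0.60, which turned to 0.29 after quantile normalization and 0.16 in the authors' deposited table. Relative to all miRNAs the family was at -0.39 (percentile 6.52). miR-30c differed by -0.60 (spot SD 0.28), beside miR-30b at -1.02. All 5 members of the miR-232724 clusters, which restrain T helper cell functions, lay below 0 with this scaling, and their median of -0.30, or -0.09 relative to all (percentile 17.5), was below 0 under each of the 12 alternatives, though only by -0.0023 when scaled to the median. Within it miR-27a differed by -0.46 (spot SD 0.17; 0.21 after quantile normalization) and miR-23a by -0.39 (spot SD 0.07). The 7 measured members of the miR-17~92 family clusters, which promote lymphocyte proliferation, had a median of -0.09, or 0.13 relative to all (percentile 80.5), which became 0.25 and -0.16 after quantile normalization. The median itself was also above 0 when scaled to the median (0.21) and in the authors' deposited table (0.41). Their members furthest from 0 were miR-19b and miR-106b, the latter at -0.45 (spot SD 0.23; 0.66 after quantile normalization).

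The miR-15/16 family, which restrains the cell cycle, had 3 of 7 members measured and a median of -0.16, or 0.05 relative to all (percentile 52.8); after quantile normalization these were 0.17 and -0.25. The median was also above 0 when scaled to the median (0.14) and in the authors' deposited table (0.19). miR-15a differed by 0.24 (spot SD 0.09), or -0.38 when scaled to bright control probes. miR-16 differed by -0.16 (spot SD 0.09), or 0.14 when scaled to the median, 0.12 after quantile normalization and 0.19 in the authors' deposited table. miR-29a and miR-29b, regulators of interferon-gamma in T cells, differed by -0.57 (spot SD 0.13) and -0.27 (spot SD 0.09), and after quantile normalization by -0.37 and 0.37. miR-181a, which sets the sensitivity of the T cell receptor in the thymus, differed by -0.15 (spot SD 0.08) and miR-181b by -0.07 (spot SD 0.14), both turning above 0 after quantile normalization (0.81 and 1.08). The pan-haematopoietic list had 4 of 5 members measured and a median of 0.29 (0.50 relative to all, percentile 88.8), which was -0.33 when scaled to bright control probes.

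A list labelled GC-rich or repeat-like late annotations held 3 of the 7 lower miRNAs. It was meant for miRNAs annotated late, whose probes often give signal in total RNA of many tissues. Whether this holds for each of its 40 members was not checked. Of the 3, miR-188-5p and miR-1224 matched a RefSeq gene symbol and miR-714 did not. Of its 13 members on the array, 6 were measured on both arrays and 4 on the WT array only. miR-714, miR-188-5p and miR-1224 were at least 2-fold lower, while miR-720 and miR-709 lay above 0. The median was -0.66, or -0.45 relative to all miRNAs, at percentile 0.71. The median was -0.12 with no filter on dim probes and -0.18 after quantile normalization, and below 0 under each of the 12 alternatives. With the WT-only members at their bounds the median was -0.65. From the list for the Sfmbt2 cluster 4 of 12 members on the array were detected, miR-669c, miR-669a, miR-466h and miR-669b, and all 4 on the WT array only. The list leaves out other miR-466 and miR-467 names on the array, such as miR-466c-5p and miR-467c, so the counts are of the list alone. From the imprinted Dlk1-Dio3 cluster miR-494 was measured on both arrays, with a log2 difference of -0.22 (spot SD 0.11; 0.41 after quantile normalization), and miR-134 was detected on the WT array only, at 29.4 against -15.1.

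**Figure D3:**
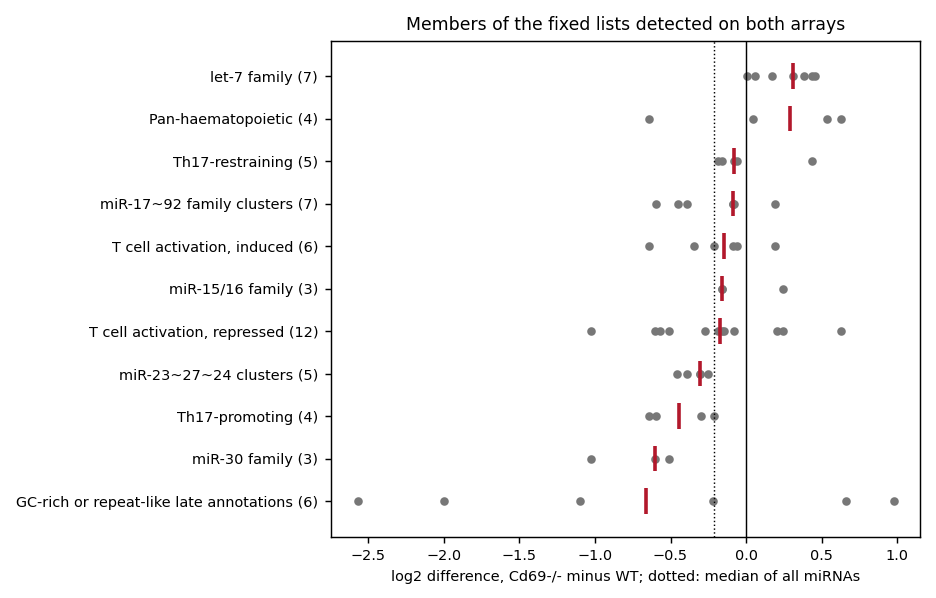
Log2 difference, Cd69-/- minus WT, of the members of 11 fixed lists measured on both arrays; grey points are miRNAs, red bars the list medians, the dotted line the median of all (-0.21), and the number of members stands in parentheses. With this scaling the let-7 median lies at 0.31 (-0.31 when scaled to bright control probes) and that of the list labelled late annotations at -0.66 (-0.12 with no filter on dim probes).

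Markers of other cells were not detected. None of the 3 myeloid, 3 erythroid, 10 stromal and endothelial, 7 epithelial and 10 other-tissue miRNAs on the array was well above background in either culture. Of the 10 viral miRNAs on the array, 0 of 195 spots were well above background in WT and 1 of 195 in Cd69-/-.

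The authors' deposited table lists log2 values of 89 miRNAs, those that Feature Extraction counted as detected on the WT array, and its columns have the same median of 6.28. In that table miR-721 stood at 7.71 in WT and at 0.14 in Cd69-/-, the lowest value of that column, which 17 miRNAs shared. Among the 65 miRNAs counted as detected on both arrays, the table had 7 at least 2-fold higher in Cd69-/-, led by miR-301a (2.496) and miR-34a (2.01), with miR-720 (1.20) and miR-146a (1.04) among the others, and 6 at least 2-fold lower. The 6 were miR-714, miR-689, miR-188-5p, miR-574-5p, miR-1224 and miR-706, all of them among the 7 found lower from the spot signals, and miR-706 was at the shared lowest value. For miR-30b the table gave -0.05. From the spot signals, miR-301a had means of 6.01 in WT and 9.98 in Cd69-/- and was not well above background on either array. miR-34a read 21.1 in WT and did not pass the detection rule there, so both differences start from dim WT signals.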

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

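The test in this part was chosen after the results were seen.

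Control probes outside the miRNA comparison were brighter on the Cd69-/- array. The Cd69-/- to WT signal ratio was 1.447 for the probes named hur_1, 1.496 for hur_2, 1.872 for hur_4, 1.571 for hur_6 and 1.347 for mr_1, each over 20 spots per array and with a spot SD of 0.09 to 0.13 in log2. What these probes bind is not given in the sources used here. The bright corner spots had a ratio of 0.992. If the whole Cd69-/- array were brighter and miRNA amounts alike, the miRNAs would have followed. But their median unscaled log2 difference was -0.228 and their upper quartile 0.028, below the lowest control value of 0.429. That argues against a brighter array as the source only if miRNA amounts were alike. A brighter array with less miRNA in the Cd69-/- sample would give the same values and cannot be told apart. A different amount of the RNA these controls bind, in the cultures or added during labelling, stays open, and so does the genotype, untested with 1 array per group.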

How the results depend on the processing

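Normexp background correction and scaling to bright control probes were chosen after the data were seen. Where no cause is named, the cause was not tested. Of the counts, 23 values over the alternatives stayed within 1.5 times that of the report and 12 did not. Of the list medians relative to all miRNAs, 86 moved by no more than the SD among members and 12 by more; another 33, under scaling by a single factor, cannot move. The list medians themselves turned sign in 19 of 131 cases: 6 after quantile normalization, 6 in the authors' table, 5 when scaled to the median and 2 when scaled to bright control probes. For single miRNAs, 191 values moved by no more than the spot SD (0.2 for a log2 bound) and 169 by more. Part of the 191 was fixed in advance. Leaving out the scaling moves each value by less than the smallest spot SD. A miRNA with 1 probe keeps its value with the brightest probe. A miRNA whose probes were all detected on both arrays keeps its value with no filter and with Feature Extraction's flag. Bounds of at least 2-fold (6) came to 3 when scaled to the median, 2 after quantile normalization, 1 after normexp, which adds an offset that shrinks dim differences, and 13 when scaled to bright control probes. miRNAs at least 2-fold higher (0) came to 1 when scaled to the median, 8 after quantile normalization, 1 with Feature Extraction's flag and 7 in the authors' table. miRNAs at least 2-fold lower (7) came to 4 after quantile normalization, 11 with no filter on dim probes, 3 after normexp and 20 with bright control probes. List medians relative to all miRNAs moved as follows. After quantile normalization Th17-promoting was -0.47, let-7 0.10, miR-15/16 -0.25, miR-17~92 -0.16 and miR-232724 -0.48. With no filter, Th17-promoting was 0.00, let-7 0.17 and miR-232724 -0.30. That setting puts undetected members, and with them the median of all 566 miRNAs, at 0 by construction. All 5 miR-232724 members were detected and their list median stayed at -0.30, so there only the median of all moved. In the authors' table Th17-promoting was -0.46, let-7 0.24 and miR-232724 -0.41. After normexp the miR-30 family was -0.11.

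No paired analysis was possible because both arrays carry replicate number 1, so the groups share fewer than 2 numbers. Leaving out a replicate was impossible with 1 array per group. The 75th percentile over all probes gave no value because it is negative (-7.11 in WT, -9.27 in Cd69-/-). Signal over background limits what can be compared: 1519 probes were detected on neither array.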

Other observations

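The tests of explanations in this part were chosen after the results were seen; the list percentiles, the quantile normalization and the use of the authors' table, on which those of the let-7 family draw, had been set earlier.

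Probes not well above background on either array also leaned to the WT side. Of 1519 such probes, 51 were brighter on the WT array by over 10 signal units and 3 on the Cd69-/- array, while the median difference of all was 0.1. The 51 probes carry 27 miRNA names. Among them were miR-466h, miR-467e, miR-669b and miR-297c of the Sfmbt2 cluster list, named after their values were seen and without a test of enrichment. miR-466h and miR-669b, like miR-134, miR-671-5p and miR-715, had already been counted as seen on the WT array only, through other probes. The 3 on the other side were probes of miR-150*, miR-7a and miR-98, the last a let-7 family member.

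The 25 miRNAs at least 2-fold lower in Cd69-/- or detected on the WT array only make up a pattern among the 80 detected. Less labelled RNA or a lower gain on the Cd69-/- array would lower all bright probes by a common factor. Yet the 83 probes with a WT signal of at least 100 had a median unscaled log2 difference of -0.289, and 24 of them were higher. Their SD was 1.06, but the 83 include the pattern's own probes, 22 probes being at least 2-fold lower. That SD thus partly follows from how the pattern was chosen and is not counted here. A blemish on the WT array would raise neighbouring spots, but the 1867 neighbours differed by a median of 0.56 signal units, against 60.9 for the pattern's own 366 spots, which lie in 168 of the 192 rows of the array. RNA other than miRNAs may contribute, since 7 of the 10 detected members of the late-annotation list are in the pattern. But 2 members were higher, and whether the probe of each member gives such signal was not checked, so this stays open. The Cd69 genotype stays open too, untested with 1 array per group. So does whatever the re-analysis mark in the WT title stands for, since only that sample carries it.

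The median of the let-7 family in Cd69-/- lay 0.52 above the median of all miRNAs, a gap that scaling by a single factor cannot move. Of the 2 alternatives with another kind of scaling, quantile normalization gave 0.097 and the authors' table gave 0.24, with an SD of 0.18 among members, so the choice of scaling could account for much of it and stays open. A culture with more resting-type miRNAs is a further candidate explanation, but the list of miRNAs that are lower after T cell activation stood at percentile 68.19 and the induced list at 54.88, which leaves it open. The genotype was not tested apart from these.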
